A study of Mus musculus with 9 samples.

How the data were processed

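Bulk RNA-seq counts were analysed for 9 libraries of whole mouse pancreas at embryonic day 18.5, 3 libraries in each of 3 groups. Per the labels' protocols, the dissected organ was pulverised in lysis buffer, total RNA was extracted with a Qiagen RNeasy Mini kit, and libraries were made with a standard Illumina procedure. Whether the libraries kept strand information is not given in the sources used here.

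The deposited files hold raw counts of reads per gene symbol, 1 file per library, with no normalization by the authors. The submitters' processing notes name FastQC, Trim Galore, HISAT2, bedtools, HTSeq and DESeq2 and the builds mm10 and GRCm38, without a role for each. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Each file lists 55453 gene symbols and 5 rows that name no gene, in the form HTSeq writes them. These 5 rows stayed out of library sizes and tests. They held 28.5% to 33.2% of the reads of a library, mostly reads aligned to several places (15.8% to 20.8%). Reads that overlapped no annotated gene were 2.45% to 4.42%, and reads that overlapped more than 1 gene were 5.14% to 5.97%. Genes with near-identical copies therefore lost reads to these rows, and the values of such genes are uncertain.

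Gene counts summed to 46817453 to 62744499 per library. Replicates of a group differed by more than counting noise: the chi-square per degree of freedom between 2 libraries of a group ran from 17.1 to 193, so no library was a repeat of another. Gene symbols were matched to GENCODE release M21 on GRCm38 for positions and gene types. It placed 54512 symbols, among them 99.2% of the genes tested. It may not be the annotation the authors counted with.

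The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, 2-sided, on the deposited counts. Library sizes were scaled by TMM (trimmed mean of M values), and genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 19166 genes. All 9 libraries entered 1 fit with a mean per group and no covariate, so that the 3 comparisons shared 1 estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values are counts scaled to the same total of gene counts, 1e6, after TMM scaling, given as mean ± SD with n = 3. Principal components were computed on log2 CPM with a prior count of 2.

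Before the data were examined, 36 gene lists were fixed, for pancreatic cell types, neighbouring and infiltrating tissues, signalling, stress and metabolism. The list of 5 sex-linked genes served only to describe the libraries, and the list of Foxa factors has only 3 genes, under the minimum of 5 tested members. The other 34 lists were tested with camera of limma 3.58.1, which asks whether the genes of a list rank higher or lower than the other genes. The preset correlation between genes was 0.01, and the test was repeated with an estimated correlation. Adjustment was over the 34 lists of a comparison. Members past the gene test were counted with adjustment over all genes and adjusted over the list alone.

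The genes named in the text followed a rule fixed together with the lists. It took Tle3, Tle4 and the study genes Foxa1, Foxa2, Neurog3, Nkx2-2, Nkx6-1, Pdx1, Ins1, Ins2, Mafa, Gcg, Sst, Ppy, Ghrl, Ptf1a, Sox9 and Mki67. It took up to 10 rises and 10 falls of largest size among called genes with at least 5 CPM in the higher group and no overlap between the replicates. It took up to 4 members with the smallest p of each list. From these, the text names a selection, and some genes that the rule took are not reported here. Genes outside the rule appear only where they are said to have been chosen after their values were seen. For a gene with 1 to 9 counts over the libraries of a group, the ratio of counts is given with an exact 95% interval in place of the fitted change. A group at 0 was set to a floor of 3 counts over the group. Intervals and floors cover counting error only.

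The alternatives were size factors of DESeq2 1.42.0 in the edgeR fit, the acinar enzyme genes left out, no filter beyond 1 count, a stricter filter of 1 CPM in at least 3 libraries, the replicate number as a block, only the 6 libraries compared, each library left out in turn, the Wald test of DESeq2, limma's voom with quality weights, and the estimated correlation for lists. The sex of the embryo as a term in the fit was added after seeing the data. For the 2 comparisons against the same controls, 20 simulations of unchanged groups gave the correlation and covariance that shared controls produce.

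Each comparison's test was tested on simulated data drawn from the real means and library sizes, with 200 genes changed, 100 by 2-fold and 100 by 4-fold. The changed genes were drawn from those with at least 1 CPM in the reference group, and the noise of each gene was drawn on its own. The shares below therefore do not cover weaker genes or libraries in which many genes shift together. For the Grg3 mutant against control, on 18257 genes, 80% of the 2-fold and 97% of the 4-fold changes were recovered, and 4.84% of calls were false. For the Grg3 Grg4 mutant against control, on 18226 genes, the shares were 72%, 97% and 3.98%. For the Grg3 Grg4 mutant against the Grg3 mutant, on 18486 genes, they were 61%, 93% and 6.10%.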

Results

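RNA of the whole pancreas was sequenced from e18.5 mouse embryos, with 3 embryos in each of 3 genotypes on a mixed C57BL6 background. Control embryos carried only Pdx1:Cre, a Cre recombinase driven by the promoter of the pancreatic transcription factor Pdx1. The other groups were labelled as carrying Pdx1:Cre with a Grg3 mutation, or with Grg3 and Grg4 mutations. Grg3 and Grg4 are Groucho proteins, co-repressors recruited by DNA-bound transcription factors, and their genes are Tle3 and Tle4. Gene counts summed to 51180550, 55030395 and 50120504 in control replicates 1, 2 and 3. They summed to 53058681, 62744499 and 53784242 in Grg3 mutant replicates 1, 2 and 3, and to 52389775, 61214013 and 46817453 in Grg3 Grg4 mutant replicates 1, 2 and 3.

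The libraries differed in sex, read from Xist and Y-linked genes. Control replicate 1, Grg3 mutant replicate 1 and all 3 Grg3 Grg4 mutant libraries were male, with Ddx3y at 30.0 to 41.1 CPM and Xist at 0.265 CPM or less. The other 4 were female, with Xist at 428 to 755 CPM. The first principal component of all genes tested held 31.6% of the variance and placed the controls between -57.8 and -37.4 and the Grg3 mutant libraries between -3.10 and 25.5. Grg3 Grg4 mutant replicate 2 stood apart from the other 2 of its group, at 70 against 27.1 and 27. That library held 172 CPM of the cardiac and fetal muscle actin Actc1, against 5.32 and 1.08 CPM in replicates 1 and 3.

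Of the targeted genes, Tle3 went against the labels, and Tle4 was higher in the libraries labelled mutant without passing the test. Tle3 (chromosome 9, 61372366 to 61418497, GRCm38) was measured at 64.8 ± 2.50 CPM in the control libraries (SD, n = 3), 153 ± 12.1 in those labelled Grg3 mutant and 135 ± 10.4 in those labelled Grg3 Grg4 mutant. It was higher than control by 1.24 (SE 0.09) and 1.05 (SE 0.09) on the log2 scale, with edgeR adjusted p of 0.00027 and 0.000558, and each of the 6 libraries labelled mutant lay above all 3 controls. Tle4 (chromosome 19, 14448150 to 14598051) was measured at 7.77 ± 0.09, 12.2 ± 2.10 and 11.6 ± 3.52 CPM (SD, n = 3), and its log2 changes of 0.65 and 0.58 did not pass (edgeR adjusted p = 0.132 and 0.155). For Tle4 too, each of the 6 libraries labelled mutant lay above all 3 controls, at 8.63 to 15.5 against 7.68 to 7.85 CPM. Between the mutant groups, Tle3 differed by -0.19 and Tle4 by -0.07 (edgeR adjusted p = 0.31 and 0.886). Counts were per whole gene, so that a transcript left after the loss of some exons would still be counted, and cells outside the Cre lineage add to both genes. Because Tle3 goes against the labels, the groups are called libraries labelled by a genotype throughout, and the directions below are between labels. The plot of the targeted genes gives each library.

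**Figure D1:**
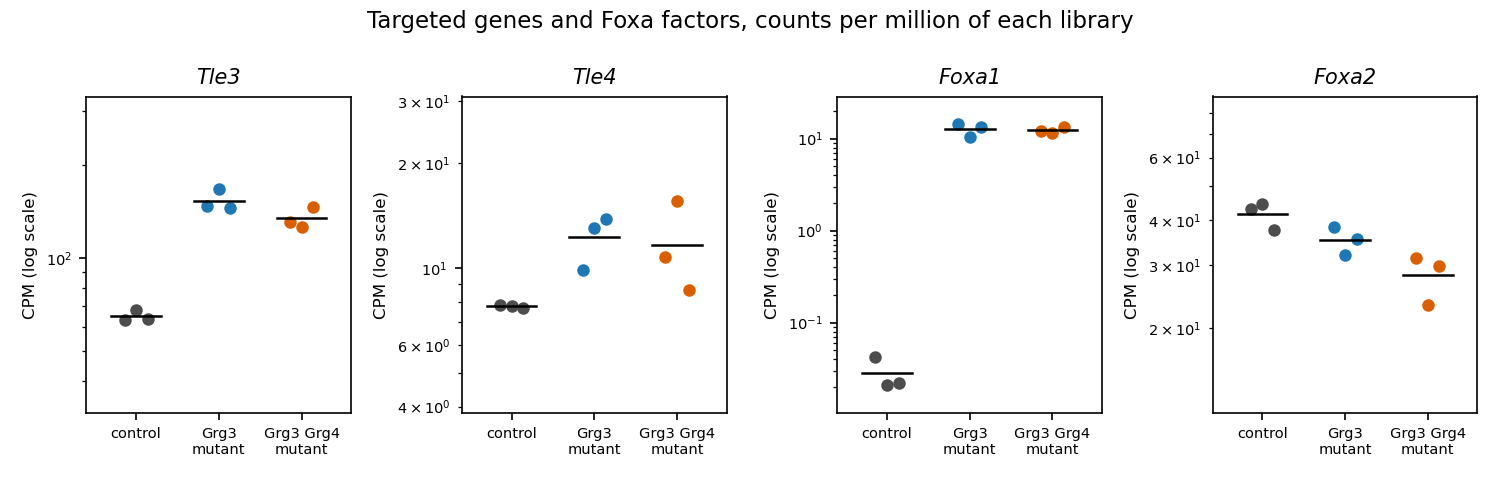
CPM (log axis) of Tle3, Tle4, Foxa1 and Foxa2 in each library, by labelled group. Points are libraries (n = 3 per group) and lines are means. Tle3 lies between 63.1 and 67.7 CPM in the controls and between 126 and 167 CPM in the other 6 libraries, and Foxa1 is near 0 in the controls.

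The comparison of the libraries labelled Grg3 mutant with control asks what differs in the pancreas when Grg3 alone is targeted. Some genes of digestive enzymes (9 of 34) were lower and some typical of liver (9 of 18) were higher in the libraries labelled Grg3 mutant, and both lists lost their calls with an estimated correlation (adjusted p = 0.258 each). The trypsinogen Prss1 fell by 2.59 (SE 0.27) on the log2 scale, from 5616 ± 171 to 932 ± 351 CPM (SD, n = 3), and the chymotrypsin-like protease Ctrl fell by 2.49 (SE 0.21). Alb, which encodes serum albumin, rose from 3.44 ± 1.76 to 298 ± 307 CPM, a log2 change of 6.43 (SE 1.0) whose 3 libraries ran from 37.9 to 636 CPM. Foxa1, a pioneer transcription factor of foregut endoderm, was nearly absent from the controls. Tle3 was higher in the same libraries, so these directions hold between labels only.

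Foxa1 (chromosome 12, 57540628 to 57546916) had 4 counts over the 3 controls and 2215 over the libraries labelled Grg3 mutant, a ratio of 442 (95% counting interval 172.3 to 1622). Its family members Foxa2 and Foxa3 were well expressed in the controls, at 41.7 ± 3.70 and 33.3 ± 1.06 CPM, and Foxa2 changed by -0.24 (edgeR adjusted p = 0.328). Foxa3 was chosen after its values were seen. Nkx6-3, a homeobox factor of the stomach antrum, rose by 5.43 (SE 0.37), from 0.282 ± 0.079 to 12.3 ± 3.82 CPM. Clca1, a secreted protein of intestinal goblet cells, had 1 count in the controls against 170, a ratio of 136 (24.01 to 5387). Cacna1i, a subunit of a T-type calcium channel, fell by 2.34 (SE 0.24), and the Reg family gene Reg3d fell by 1.68 (SE 0.22).

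Of 34 acinar enzyme genes, 9 fell and 25 did not pass, 16 fell adjusted over the list alone, and the list's median log2 change was -0.56. Camera called it lower (limma adjusted p = 4.17e-30), with an adjusted p = 0.258 with an estimated correlation. Prss3 fell by 2.26 (SE 0.27) and the lipase-related Pnliprp2 by 1.22 (SE 0.17). Prss1 and Prss3 belong to a cluster of near-identical trypsinogen genes whose reads the counting could split, so their single values are uncertain. In the same libraries, 9 of 18 liver genes rose (16 adjusted over the list alone) with a median of 5.34, and the list was called higher (limma adjusted p = 7.1e-24, and adjusted p = 0.258 with an estimated correlation). Afp rose by 5.91 (SE 0.97). The fibrinogen genes Fga and Fgg had 5 counts each over the controls, 4 of them in control replicate 1, with ratios of 1066 (456.5 to 3283) and 606 (259.5 to 1868). Fga had 5215, 258 and 1208 counts in Grg3 mutant replicates 1, 2 and 3. Over all alternatives the log2 change was from 8.53 to 11.63 for Fga and from 7.84 to 10.81 for Fgg. Muscle genes had a median of 2.41 with 0 of 15 past the gene test (4 adjusted over the list alone), and the list was called higher (limma adjusted p = 7.23e-07, and adjusted p = 0.412 with an estimated correlation). Myh11, a smooth muscle myosin, stood at 110 ± 81.8 CPM against 19.5 ± 1.72 (edgeR adjusted p = 0.0804).

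Of 25 beta cell genes, 3 fell (5 adjusted over the list alone, where 1 rose). These were Glp1r, the GLP-1 receptor, which fell by 1.57 (SE 0.26), G6pc2, the islet glucose-6-phosphatase, by 1.48 (SE 0.29), and Prlr, the prolactin receptor, by 1.47 (SE 0.30). The list's median was -0.32 and camera called it lower (limma adjusted p = 9.01e-05, and adjusted p = 0.46 with an estimated correlation). The insulin genes Ins1 and Ins2 and the beta cell factor Mafa had log2 changes of -0.46, -0.58 and -0.42 and did not pass (edgeR adjusted p = 0.466, 0.32 and 0.371). Neurog3, the factor that starts endocrine differentiation, had 34.2 ± 1.79 against 19.3 ± 3.87 CPM, a change of 0.83 that did not pass (edgeR adjusted p = 0.0917). Nkx6-1 had 0.51 and Sst 0.67, with edgeR adjusted p of 0.0904 and 0.146. Changes of Pdx1 (-0.23), Nkx2-2 (0.12), Gcg (-0.52), Ppy (0.30), Ghrl (0.37), Ptf1a (0.39), Sox9 (-0.10) and Mki67 (-0.31) did not pass either (edgeR adjusted p from 0.286 to 0.744). The delta, PP and epsilon cell list was called higher with a median of 0.35 (limma adjusted p = 0.0124, and adjusted p = 0.665 with an estimated correlation), and of its 13 genes only Rbp4 passed, a rise of 0.67 (SE 0.14).

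The cholesterol synthesis list had a median of -0.43 with 1 of 22 called. Its mean log2 CPM, relative to all 9 libraries, was -0.47, -0.38 and 0.15 in Grg3 mutant replicates 1, 2 and 3. In the controls it was from 0.09 to 0.34, so replicate 3 lay inside the control range. Adjusted over the list alone 11 fell, and camera called the list lower (limma adjusted p = 3.57e-11, and adjusted p = 0.412 with an estimated correlation). The hypoxia and glycolysis list had a median of 0.39, with 5 of 24 members below 0 and 3 called (11 adjusted over the list alone). The glucose transporter Slc2a1 rose by 0.70 (SE 0.13), Pfkl by 0.52 (SE 0.10) and P4ha1 by 0.37 (SE 0.06). Camera called the list higher (limma adjusted p = 7.23e-07, and adjusted p = 0.412 with an estimated correlation). Of 21 BMP and TGF-beta targets, Id1 rose by 0.75 (SE 0.14) and Skil, itself a repressor of that pathway, fell by 0.42 (SE 0.08), with 9 higher and 1 lower adjusted over the list alone and a median of 0.29 (limma adjusted p = 7.31e-05, and adjusted p = 0.412 with an estimated correlation). The macrophage and leukocyte list had a median of 0.67 with 0 of 27 past the gene test (5 adjusted over the list alone; limma adjusted p = 1.27e-06, and adjusted p = 0.46 with an estimated correlation). Of 16 intestine genes, 3 were called (9 higher and 1 lower adjusted over the list alone): Clca1, Lgals4, a rise of 1.39 (SE 0.25), and Apob, a rise of 5.31. Apob stood at 12.6, 0.645 and 3.08 CPM in Grg3 mutant replicates 1, 2 and 3, and Alb at 636, 37.9 and 220. The list's mean log2 CPM, relative to all 9 libraries, was 1.59, 0.05 and 0.18 in these replicates. In the controls it was from -1.09 to -0.15. The list's median log2 change was 1.60 and camera called it higher (limma adjusted p = 0.000128, and adjusted p = 0.258 with an estimated correlation). The Groucho family list was called higher at the same 2 values with a median of 0.15, and Tle3 was the 1 member of 6 past the gene test (3 adjusted over the list alone). Cell cycle, adipocyte, erythroid and lymphoid lists were called higher with medians of 0.10, 0.50, 0.47 and 1.22, and 0 members passed the gene test (2, 1, 0 and 0 adjusted over the list alone). Their limma adjusted p ran from 0.0154 to 0.0354, and adjusted p from 0.412 to 0.822 with an estimated correlation.

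In total 268 of 19166 genes were called in the libraries labelled Grg3 mutant against control (135 higher and 133 lower; edgeR quasi-likelihood test), 138 of them by at least 2-fold, and 3661 had an unadjusted p under 0.05. The replicates did not overlap for 24.6% of genes, where chance gives 10%. The count was 32 without control replicate 3, 44 without control replicate 2, 75 without Grg3 mutant replicate 1, 169 with embryo sex as a term, 421 by limma's voom, 586 with no filter and 1323 by DESeq2. Of the 23 named genes called besides Tle3 and Apob, only Foxa1, Nkx6-3, Prss1, Prss3, Ctrl and Cacna1i passed without control replicate 2 or 3. The calls of 5 lists (delta, PP and epsilon cell, cell cycle, lymphoid, erythroid, adipocyte) each ended without at least 1 of control replicates 1 and 2 and Grg3 mutant replicates 1 and 2.

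The other 19 lists did not pass in this comparison. They were pan-endocrine secretory (median -0.16), endocrine progenitor (0.16), alpha cell (0.09), acinar transcription factor (-0.24), duct (17 of 34 members above 0), multipotent and trunk progenitor (-0.07), Reg family and acinar injury (0.14), endothelium (0.10), neural and Schwann (0.44), mesenchyme (0.09), mesothelium (-0.03), stomach (1.12), mitochondrially encoded (0.17), cell cycle inhibitor and p53 target (0.08), Notch pathway (0.06), Wnt target (0.10), ER stress (-0.02), immediate early and heat shock (0.19) and interferon response (-0.10), with limma adjusted p from 0.0618 to 0.992. The median and the mean differed in sign for the Reg family, alpha cell, progenitor and duct lists, and the test's direction followed the mean except for the progenitor list.

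The comparison of the libraries labelled Grg3 Grg4 mutant with control asks what differs when both genes are targeted. Some genes of the beta cell list (9 of 25) were lower in the libraries labelled Grg3 Grg4 mutant, all 3 of them male. The list's call was lost with an estimated correlation (limma adjusted p = 0.175). Ins2 fell by 1.52 (SE 0.30) on the log2 scale, from 2687 ± 193 to 936 ± 420 CPM (SD, n = 3), and Mafa, an activator of insulin transcription, fell by 1.35 (SE 0.24). Some digestive enzyme genes were lower as well, with Prss1 at 687 ± 153 CPM (a log2 change of -3.03, SE 0.27) and Ctrl at 512 ± 56.8 CPM (-2.69, SE 0.22). Alb stood at 477 ± 294 CPM, a rise of 7.11 (SE 1.03). Tle3 was higher in these libraries too, so the directions hold between labels only.

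Of 25 beta cell genes, 9 fell (18 adjusted over the list alone), and the median was -0.60. Camera called the list lower (limma adjusted p = 1.06e-19, and adjusted p = 0.175 with an estimated correlation). Glp1r fell by 2.08 (SE 0.26), G6pc2 by 1.80 (SE 0.30), the granule protein gene Sytl4 by 1.11 (SE 0.20), the neuropeptide gene Npy by 2.56 (SE 0.52) and Pdx1 by 0.60 (SE 0.11). Ins1 changed by -1.43 and did not pass (edgeR adjusted p = 0.0551). Of 26 pan-endocrine secretory genes, 3 fell (14 adjusted over the list alone) with a median of -0.55: the prohormone-processing gene Cpe by 0.75 (SE 0.12) and the secretogranins Scg2 and Scg5 by 1.07 (SE 0.20) and 1.19 (SE 0.24). That list was called lower (limma adjusted p = 5.52e-12, and adjusted p = 0.367 with an estimated correlation). Chga changed by -1.59 and did not pass (edgeR adjusted p = 0.0522). Among genes of other endocrine cells and their progenitors, Gcg (-0.88), Sst (-0.49), Ppy (-0.54), Ghrl (-0.34), Neurog3 (0.25), Neurod1 (-0.87), Nkx2-2 (-0.15) and Nkx6-1 (0.05) did not pass, with edgeR adjusted p from 0.0798 to 0.858.

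Acinar enzyme genes fell in 11 of 34 cases (20 adjusted over the list alone), with a median of -0.76, and the list was called lower (limma adjusted p = 9.34e-35, and adjusted p = 0.196 with an estimated correlation). Prss3 fell by 2.44 (SE 0.27), with the same uncertainty between trypsinogen copies, and Pnliprp2 by 1.25 (SE 0.17), while Cpa1, at 11980 ± 280 against 22010 ± 1922 CPM, changed by -0.88 and did not pass (edgeR adjusted p = 0.0952). Of 14 genes of the Reg family and acinar injury list, 3 fell (4 adjusted over the list alone): Reg1 by 1.83 (SE 0.34), Reg3d by 1.92 (SE 0.22) and the trefoil factor Tff2 by 1.69 (SE 0.21). The list had a median of -0.36 and was called lower (limma adjusted p = 0.000159, and adjusted p = 0.34 with an estimated correlation). The acinar regulator Ptf1a changed by 0.03 (edgeR adjusted p = 0.96).

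Foxa1 had 2118 counts against 4 in the controls, a ratio of 433 (95% counting interval 168.9 to 1591), and Foxa2 fell by 0.57 (SE 0.13), a call that ended in 10 of 15 alternatives, among them the fit with sex and leaving out any 1 of the 6 libraries (log2 change from -0.66 to -0.45). Multipotent and trunk progenitor genes were called lower, with a median of -0.22 and 3 of 19 fallen (4 lower and 1 higher adjusted over the list alone), which were Pdx1, Foxa2 and the Notch effector Rbpj, which fell by 1.09 (SE 0.24) (limma adjusted p = 0.00897, and adjusted p = 0.367 with an estimated correlation). Sox9 changed by -0.20 and did not pass (edgeR adjusted p = 0.43). Of 34 duct genes, the water channel Aqp1 fell by 0.66 (SE 0.13) and 33 did not pass (4 fell adjusted over the list alone), with a median of -0.18 (limma adjusted p = 0.00954, and adjusted p = 0.62 with an estimated correlation). Of 25 immediate early and heat shock genes, the chaperone gene Hspa8 fell by 0.50 (SE 0.09; 3 fell adjusted over the list alone) with a median of -0.15 (limma adjusted p = 0.0145, and adjusted p = 0.582 with an estimated correlation). The Groucho family list was called higher with a median of 0.36, with Tle3 and Tle2, a rise of 0.55 (SE 0.11), as the 2 called of 6 (3 adjusted over the list alone; limma adjusted p = 0.000159, and adjusted p = 0.175 with an estimated correlation).

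Lists of liver, muscle and erythroid genes were called higher in this group with the preset correlation only. Of 18 liver genes, 11 rose and all 18 did so adjusted over the list alone, with a median of 5.99, or 5.78 with genes absent from the controls set at their bound (limma adjusted p = 2.99e-30, and adjusted p = 0.196 with an estimated correlation). Afp rose by 7.05 (SE 1.01), and Fga and Fgg had ratios of 1317 (564.2 to 4058) and 711.1 (304.5 to 2191) over 5 control counts each. Over all alternatives the log2 change was from 9.14 to 11.88 for Fga and from 8.29 to 10.99 for Fgg. Muscle genes had a median of 5.10 with 0 of 15 past the gene test (14 adjusted over the list alone; limma adjusted p = 6.68e-09, and adjusted p = 0.401 with an estimated correlation). Tnnt3, a fast muscle troponin, was at 178 CPM in replicate 2 and at 4.62 and 1.08 CPM in replicates 1 and 3, and its log2 change of 7.29 was 2.86 without replicate 2. The mean log2 CPM of the list, relative to all 9 libraries, was 0.97, 4.2 and -0.8 in replicates 1, 2 and 3, so replicate 2 carries most of the rise, and from -1.88 to -1.67 in the controls. Erythroid genes had a median of 1.31 with 0 of 20 past the gene test, also adjusted over the list alone (limma adjusted p = 9.54e-06, and adjusted p = 0.582 with an estimated correlation). Their mean log2 CPM, relative to all 9 libraries, was 1.44, 0.28 and 0.6 in Grg3 Grg4 mutant replicates 1, 2 and 3. In control replicates 1, 2 and 3 it was -1.1, -1.23 and 0.19, so control replicate 3 lay close to Grg3 Grg4 mutant replicate 2. The transferrin receptor gene Tfrc, at 44.2 ± 13.1 against 26.2 ± 6.99 CPM, did not pass (edgeR adjusted p = 0.111).

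Another 4 lists were called lower: delta, PP and epsilon cell (median -0.15), endocrine progenitor (-0.11), ER stress (-0.21) and mitochondrially encoded (-0.21), with cholesterol synthesis (-0.22) as well. Cell cycle (0.16), BMP and TGF-beta target (0.20) and hypoxia and glycolysis (0.21) were called higher. In these 8 lists the gene test passed only Skil, a fall by 0.37 (SE 0.08), and adjusted over the list alone 8 BMP and TGF-beta targets were higher, while Skil and 1 member each of the delta and ER stress lists were lower. Their limma adjusted p ran from 0.000818 to 0.0482, and adjusted p was 0.693 for each with an estimated correlation. The cell cycle marker Mki67 had 256 ± 26.5 against 183 ± 46.2 CPM and did not pass (edgeR adjusted p = 0.145). The other 15 lists did not pass, with limma adjusted p from 0.0674 to 0.948. Their medians were -0.18 for endothelium, 0.81 for lymphoid and spleen, 0.06 for alpha cell, -0.23 for interferon response, -0.22 for acinar transcription factor, 0.09 for intestine, 0.24 for macrophage and leukocyte, 0.10 for adipocyte, -0.10 for neural and Schwann, 0.08 for mesothelium, -0.05 for mesenchyme, 0.28 for stomach and 0.18 for Wnt target, with 0.04 for Notch pathway and 0.04 for cell cycle inhibitor and p53 target. Median and test, or median and mean, differed in sign for the alpha cell, neural, mesenchyme, stomach and Notch lists.

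In total 410 of 19166 genes were called in the libraries labelled Grg3 Grg4 mutant against control (238 higher and 172 lower; edgeR quasi-likelihood test), 217 of them by at least 2-fold, and 3866 had an unadjusted p under 0.05. The replicates did not overlap for 29.1% of genes, where chance gives 10%. The count was 30 with embryo sex as a term (all 3 libraries labelled Grg3 Grg4 mutant were male, and 2 of 3 controls were female), 50, 55 and 120 without control replicates 3, 2 and 1, 164 and 160 without Grg3 Grg4 mutant replicates 1 and 2, 750 with only the 6 libraries compared, 930 with no filter, 1033 by limma's voom and 1471 by DESeq2. Of the 28 named genes called besides Tle3, the calls of 22, among them Ins2, Mafa, Pdx1, Glp1r and Alb, ended with sex as a term, those of 21 and 20 without control replicates 2 and 3, and those of 16, 15, 13 and 8 without control replicate 1 and Grg3 Grg4 mutant replicates 1, 2 and 3. Foxa1, Prss1, Prss3, Ctrl, Reg3d and Tff2 passed in each alternative that gave a value. Over all alternatives, sex included, the log2 change was from -1.95 to -1.32 for Ins2, from -1.56 to -1.25 for Mafa, from -0.72 to -0.48 for Pdx1, from -2.42 to -1.90 for Glp1r and from 6.01 to 7.62 for Alb, so these calls ended while most of the change remained. The calls of the duct list, the immediate early list and the 8 lists with no or 1 called member each ended in at least 1 alternative, by leaving out 1 of the 6 libraries or, for cholesterol synthesis, with sex as a term.

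**Figure D2:**
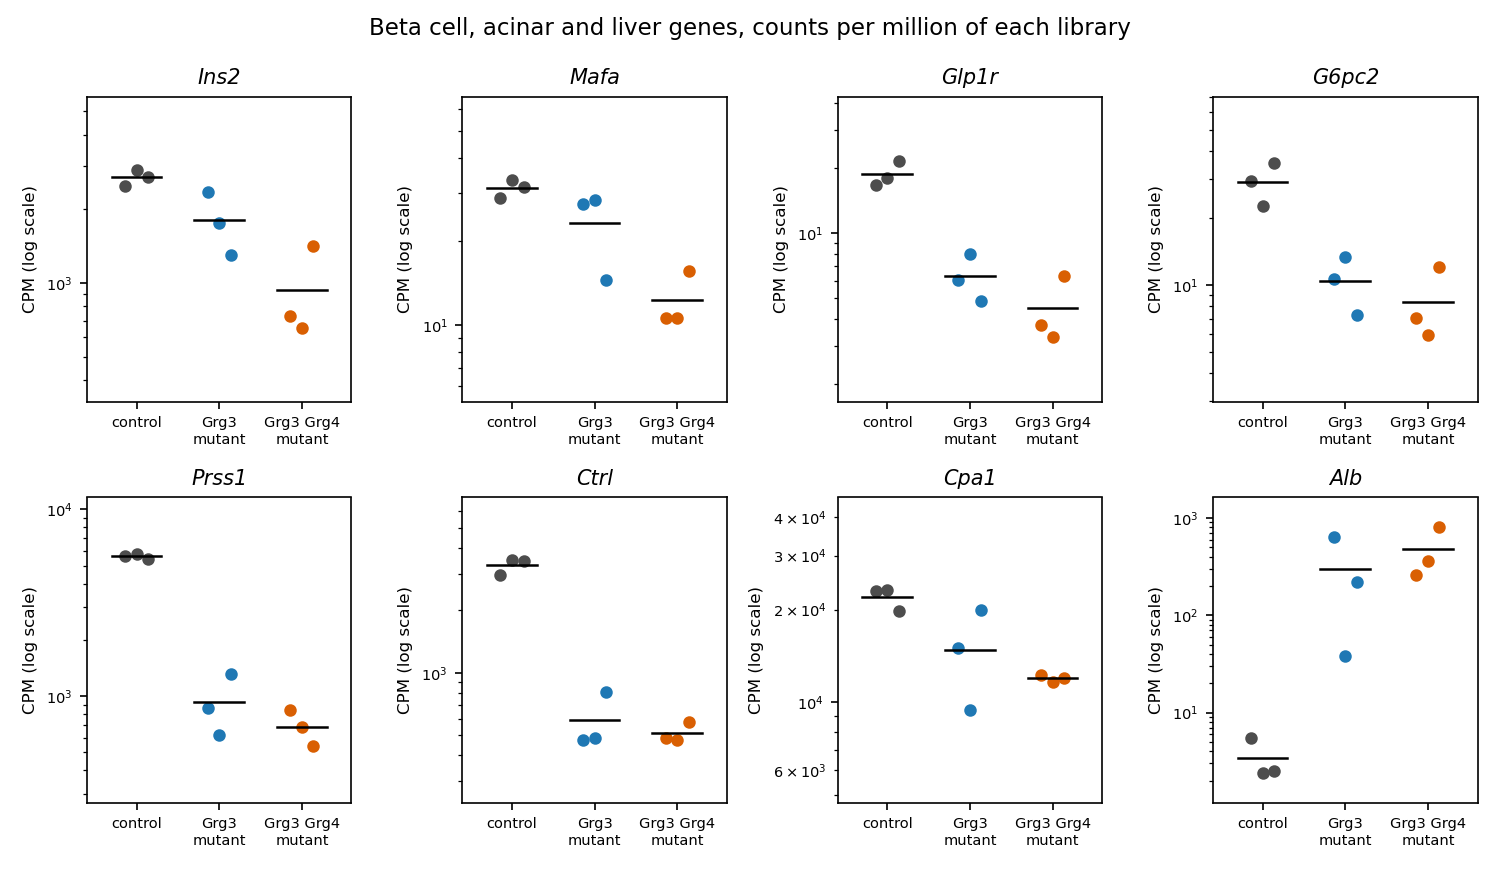
CPM (log axis) of beta cell genes (Ins2, Mafa, Glp1r, G6pc2), acinar genes (Prss1, Ctrl, Cpa1) and the liver gene Alb in each library, by labelled group. Points are libraries (n = 3 per group) and lines are means. Prss1 is at 5443 to 5784 CPM in the controls and at 537.5 to 1311 CPM in the other 6 libraries.

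The comparison of the libraries labelled Grg3 Grg4 mutant with those labelled Grg3 mutant asks what the mutation of Grg4 adds. Gast, the gastrin gene, fell by 1.15 (SE 0.18) on the log2 scale, from 19.4 ± 1.65 to 8.71 ± 1.89 CPM (SD, n = 3), and Clec3b, which encodes tetranectin, fell by 1.03 (SE 0.10). Of the endocrine lists, all but the alpha cell list were called lower in the libraries labelled Grg3 Grg4 mutant with the preset correlation, none was with an estimated correlation (adjusted p = 0.51 each), and 0 of their members passed the gene test. Mean log2 CPM, relative to all 9 libraries, is given for replicates 1, 2 and 3 of each label, whose numbers mark no known pairing. For beta cell it was -0.57, -0.62 and -0.12 for Grg3 Grg4 mutant against 0.15, 0.11 and -0.21 for Grg3 mutant. For pan-endocrine secretory it was -0.48, -0.58 and 0.05 against 0.16, 0.21 and -0.12. For endocrine progenitor it was -0.27, -0.32 and 0.15 against 0.21, 0.33 and -0.01. For delta, PP and epsilon cell it was -0.55, -0.25 and -0.01 against 0.11, 0.62 and 0. In each list, Grg3 Grg4 mutant replicates 1 and 2 lay below all Grg3 mutant libraries. Replicate 3 lay within their range or, for delta, PP and epsilon cell, just below it. Tle4 did not differ beyond its spread between these groups, so its level does not tell the labels apart and directions hold between labels only.

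Clca1 had 1 count against 170, a ratio of 166 (95% counting interval 29.36 to 6586). Ciapin1, a factor of iron-sulphur cluster assembly, fell by 0.53 (SE 0.07) and the collagen prolyl hydroxylase gene P4ha1 by 0.48 (SE 0.06). Genes that rose were Leng8 by 0.88 (SE 0.12), Pnisr by 0.77 (SE 0.12), the small nucleolar RNA host gene Snhg17 by 0.67 (SE 0.11), the Mediator subunit gene Med12 by 0.66 (SE 0.09) and Brpf3, a subunit of histone acetyltransferase complexes, by 0.63 (SE 0.08). Reads that overlapped no annotated gene were 4.12% ± 0.28 in these libraries, against 2.67% ± 0.30 in those labelled Grg3 mutant (SD, n = 3; exact permutation test, 2-sided p = 0.1, the smallest it can give).

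The pan-endocrine secretory list had a median of -0.44 and 9 of 26 lower adjusted over the list alone (limma adjusted p = 4.06e-08, and adjusted p = 0.51 with an estimated correlation). The beta cell list had a median of -0.36 and 13 of 25 lower adjusted over the list alone, with the same 2 adjusted p. The delta, PP and epsilon cell list had a median of -0.63, with all 13 below 0 and 6 lower adjusted over the list alone (limma adjusted p = 4.4e-08, and adjusted p = 0.51 with an estimated correlation). Over all genes 0 members of these 3 lists passed. The closest were the delta cell gene Rbp4 (-0.82) and the peptide YY gene Pyy (-0.97), both with an edgeR adjusted p of 0.0518, and Sst, with 187 ± 61.9 against 416 ± 82.5 CPM (edgeR adjusted p = 0.0716). Ins1 (-0.96), Ins2 (-0.95), Mafa (-0.93), Ucn3 (-1.50), Ffar1 (-0.82), Scg2 (-0.94), Ppy (-0.85) and Ghrl (-0.71) did not pass, with edgeR adjusted p from 0.0815 to 0.178. The endocrine progenitor list had a median of -0.31 with 0 of 24 past the gene test, also adjusted over the list alone (limma adjusted p = 5.8e-05, and adjusted p = 0.51 with an estimated correlation). Neurog3 (-0.58), Insm1 (-0.68), Nkx2-2 (-0.27), Nkx6-1 (-0.45), Pdx1 (-0.36), Gcg (-0.36), Foxa1 (-0.04), Foxa2 (-0.33), Ptf1a (-0.36) and Sox9 (-0.10) did not pass, with edgeR adjusted p from 0.143 to 0.905.

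Further lists called lower were endothelium (median -0.27), macrophage and leukocyte (-0.35), mitochondrially encoded (-0.31), immediate early and heat shock (-0.28), duct (-0.15), neural and Schwann (-0.41), hypoxia and glycolysis (-0.14), multipotent and trunk progenitor (-0.19), intestine (-0.41), Reg family and acinar injury (-0.31) and stomach (-0.91). In these 11 lists, P4ha1 and Clca1 alone passed the gene test, and from 0 to 5 members of a list were lower adjusted over the list alone, with 1 member higher in each of the neural, progenitor and intestine lists. The endothelial genes Cldn5 (-0.60) and Ramp2 (-0.63), the complement gene C1qc (-0.64) and Jun (-0.42) did not pass, with edgeR adjusted p from 0.0984 to 0.167. Cholesterol synthesis (0.20, from -0.43 and -0.22 against control) and erythroid genes (0.72) were called higher with 0 members past the gene test. The limma adjusted p of these 13 lists ran from 2.13e-05 to 0.0218, and their adjusted p from 0.51 to 0.732 with an estimated correlation. Mki67 had 256 ± 26.5 against 147 ± 12.6 CPM, a change of 0.80 that did not pass (edgeR adjusted p = 0.081), and the cell cycle list was not called (median 0.06, limma adjusted p = 0.383).

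The other lists did not pass, with limma adjusted p from 0.0609 to 0.936. Acinar enzyme genes had a median of -0.02 and liver genes of 0.25. Muscle genes had a median of 3.64 with 8 of 15 higher adjusted over the list alone, a value carried by Grg3 Grg4 mutant replicate 2: the mean log2 CPM of the list, relative to all 9 libraries, was 0.97, 4.2 and -0.8 in the libraries labelled Grg3 Grg4 mutant and 0.56, -0.04 and 0.48 in those labelled Grg3 mutant. The remaining medians were -0.11 for BMP and TGF-beta target, -0.17 for alpha cell, -0.12 for ER stress, -0.17 for interferon response, -0.05 for cell cycle inhibitor and p53 target, -0.18 for mesenchyme, -0.19 for adipocyte, -0.01 for mesothelium, -0.11 for Notch pathway, -0.26 for lymphoid and spleen, -0.07 for acinar transcription factor, 0.05 for Wnt target and -0.07 for Groucho family. Median and test, or median and mean, differed in sign for the adipocyte, mesothelium, Wnt target and Groucho family lists.

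In total 36 of 19166 genes were called between the libraries labelled Grg3 Grg4 mutant and Grg3 mutant (25 higher and 11 lower; edgeR quasi-likelihood test), 15 of them by at least 2-fold, and 3319 had an unadjusted p under 0.05. The replicates did not overlap for 21.1% of genes, where chance gives 10%. The count was 4 with embryo sex as a term, 6 without Grg3 mutant replicate 1, 9, 11 and 10 without Grg3 Grg4 mutant replicates 1, 2 and 3, 10 with only the 6 libraries compared, 75 with the stricter filter, 228 with no filter and 877 by DESeq2. With sex as a term 0 of the 10 genes named here as called passed, although over all alternatives the log2 change was from -1.06 to -0.91 for Clec3b, from 0.76 to 0.94 for Leng8 and from 0.63 to 0.75 for Med12. Clec3b passed in each other alternative, and the other 9 did not pass without Grg3 mutant replicate 1 or any 1 of the Grg3 Grg4 mutant replicates; the calls of 10 lists (duct, endothelium, macrophage, erythroid, neural, intestine, stomach, Reg family, cholesterol synthesis, hypoxia) each ended without at least 1 of Grg3 mutant replicates 1, 2 and 3 and Grg3 Grg4 mutant replicates 1 and 2.

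**Figure D3:**
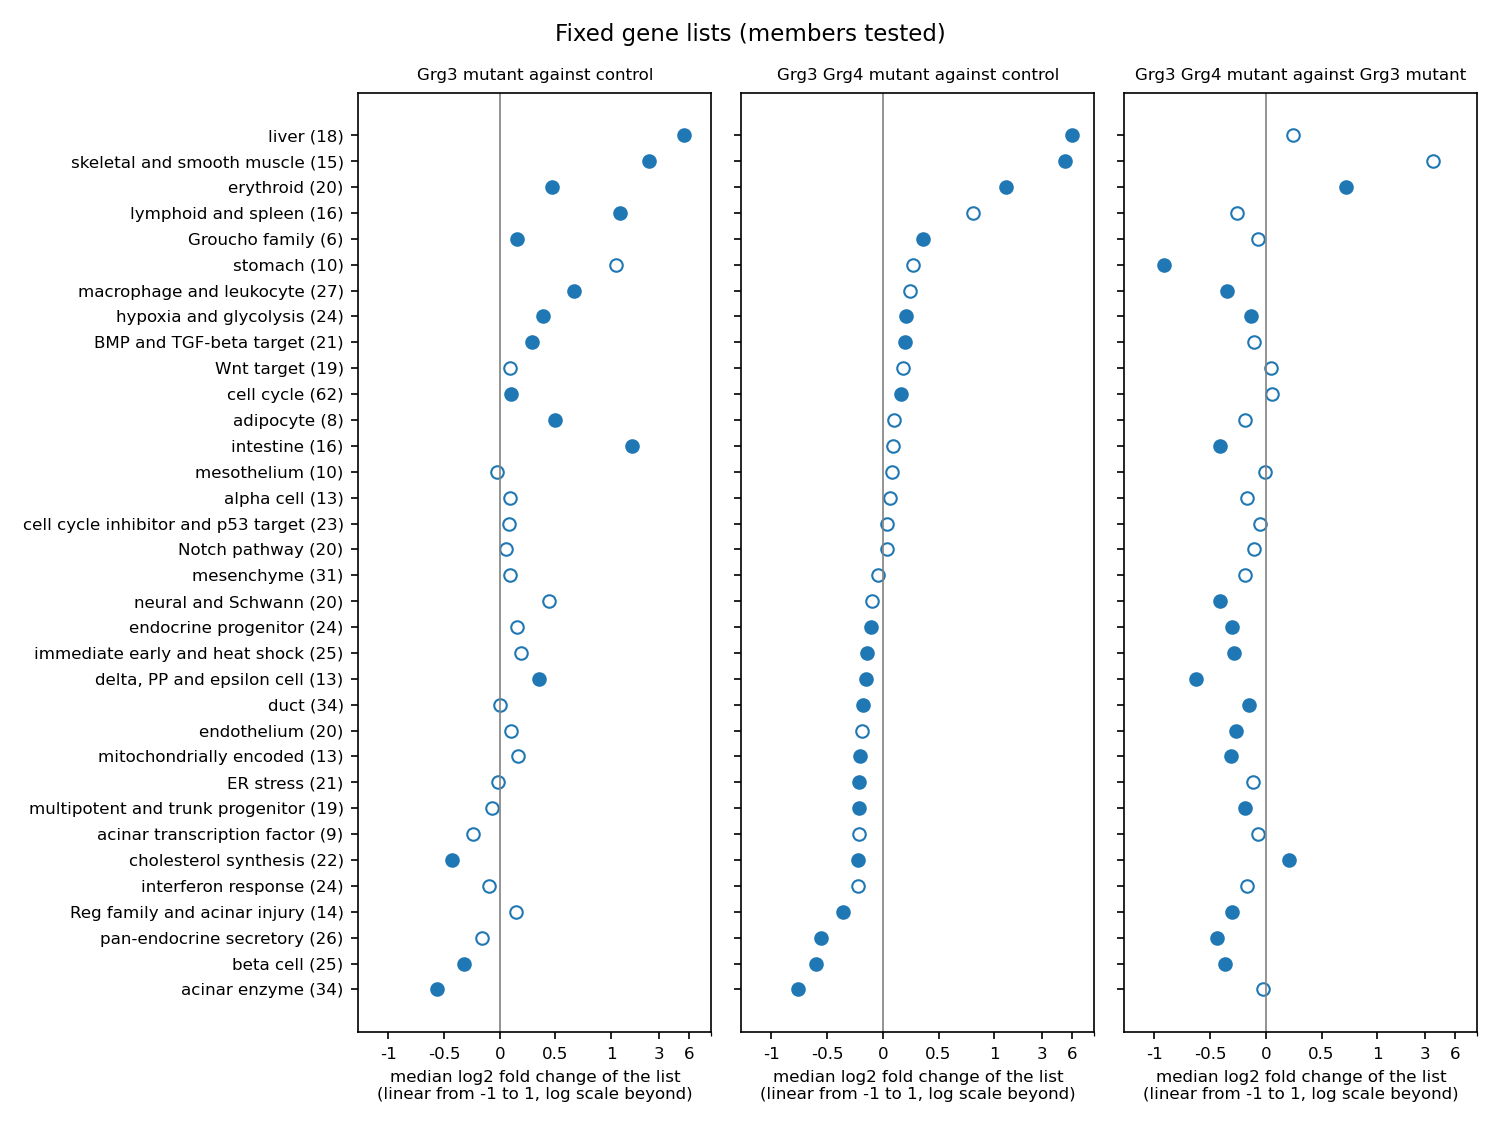
Median log2 fold change of the 34 gene lists tested, in the 3 comparisons between labelled groups. Points are lists with the number of members tested in brackets, and filled points were called by camera with the preset correlation at an adjusted p under 0.05. The axis is linear from -1 to 1 and logarithmic beyond. With an estimated correlation 0 lists were called in any of the 3 comparisons, and the preset correlation called 15, 19 and 17.

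The comparisons against control shared genes. The same direction was called in both for 128 genes, 64 higher and 64 lower, and 0 were called in opposite directions. Independent lists of these sizes would share 1.68 higher and 1.19 lower, and how many shared calls the common controls add was not tested. The log2 changes of all genes correlated with a Pearson r of 0.677 across genes, which are not independent replicates, against 0.508 in the simulations, and had the same sign for 68.4% of genes against 66.8%. The covariance was 0.392 against 0.0691 in the simulations, a difference of 0.323. The 3 controls are too few to give each comparison its own, so part of the shared calls may come from the shared controls. The shared count was 25, 28 and 59 without control replicates 3, 2 and 1, 48 without Grg3 mutant replicate 1, 62 without Grg3 Grg4 mutant replicate 1, 19 with embryo sex as a term, 202 by voom, 264 with no filter and 499 by DESeq2.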

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

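The permutation test of the reads outside annotated genes was chosen only after the values had been seen. Reads that overlapped no annotated gene, a count outside the gene measurements, were 4.12% ± 0.28 of reads in the libraries labelled Grg3 Grg4 mutant (3.86% to 4.42%), above the controls at 2.90% ± 0.27 (2.58% to 3.09%; exact permutation test, 2-sided p = 0.1, the smallest that 3 against 3 libraries can give), while those labelled Grg3 mutant were at 2.67% ± 0.30. Reads set aside for low alignment quality were 1.18% ± 0.06 in the libraries labelled Grg3 mutant (1.14% to 1.25%), above the controls at 1.09% to 1.13%. The same share was 1.24% ± 0.03 in the libraries labelled Grg3 Grg4 mutant (1.21% to 1.26%).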

How the results depend on the processing

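The fit with embryo sex as a term was the one alternative chosen only after the results were seen. Of 1787 values of 120 named gene results under the alternatives, 1418 kept their direction and their side of the threshold, 296 lost the call, 64 gained one and 9 changed sign, 0 of them for a called gene. Against 268 genes called for the libraries labelled Grg3 mutant, the counts were 586 with no filter, 169 with sex, 1323 by DESeq2, 421 by voom, and 32 (without control replicate 3) to 289 (without Grg3 mutant replicate 2) with a library left out. Against 410 for Grg3 Grg4 mutant, they were 930, 30, 1471, 1033 in the same order, 750 with only the 6 libraries compared, and 50 (without control replicate 3) to 320 (without Grg3 Grg4 mutant replicate 3). Against 36 between the mutant labels, they were 228, 4 and 877 with no filter, sex and DESeq2, 75 with the stricter filter, 10 with only the 6 libraries, and 6 to 49 (without Grg3 mutant replicates 1 and 2). The 128 shared genes became 264, 19, 499 and 202 with no filter, sex, DESeq2 and voom, and 25 (without control replicate 3) to 164 (without Grg3 mutant replicate 2). With an estimated correlation 0 lists were called in each comparison by camera, where the preset one called 15, 19 and 17. The cause of these shifts was not tested. Same-numbered libraries deviated from their groups with correlations of -0.09 to 0.09, and 2 of 9 libraries were closest to their own number. With 3 libraries per group, these values cannot exclude something shared. The number also carried sex, as replicate 1 was male in each group. Replicates 2 and 3 were female in the control and Grg3 mutant groups, so a block on the number partly takes up sex. With the number as a replicate block, 167, 254 and 11 genes were called. Tle4 against control had 0.65 by DESeq2 with an adjusted p of 0.0396 for Grg3 mutant (0.0396 to 0.342 over the alternatives). Between the mutant labels it had 0.08 with sex and -0.34 to 0.10 with a library left out, against -0.07. Other signs changed only with a library left out: Nkx6-1 from -0.08 to 0.18, Nkx2-2 from -0.35 to 0.01, Neurog3 from -0.01 to 0.46 and Ptf1a from -0.01 to 0.08 for Grg3 Grg4 mutant, and Foxa1 from -0.17 to 0.05 and Sox9 from -0.28 to 0.03 between the mutant labels. The effect of depth was not tested by thinning, and at these totals 61% to 80% of simulated 2-fold changes were recovered, among genes of at least 1 CPM.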

Other observations

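The tests on liver RNA, stomach and intestine, exchanged labels, the Foxa1 level and an even acinar fall were chosen only after the results they bear on were seen, the test on linked loci was added after the pseudogene odds ratio had been seen, and the genes in the next 2 paragraphs were chosen after their values were seen. Several genes set the controls apart from all 6 libraries labelled mutant. Ifi202b, an interferon-inducible gene, had 241 counts over the controls and 0 in the other groups, at least 101-fold and 98.2-fold lower against a floor of 3 counts over the group. The pseudogene Rps26-ps1 stood at 85.5 ± 9.14 CPM in the controls and at 7.68 ± 0.58 and 6.44 ± 0.41 in the libraries labelled Grg3 mutant and Grg3 Grg4 mutant, while the ribosomal protein gene Rps26 stood at 555 ± 59.0, 816 ± 67.0 and 682 ± 39.9. Rpl34-ps1 had 54 ± 4.73, 14.7 ± 2.70 and 11.4 ± 2.10 CPM, and Rpl34 131 ± 7.71, 256 ± 35.3 and 203 ± 17.0. A pseudogene and its parent can exchange reads, so these values are uncertain. Gast rose from 0.925 ± 0.21 CPM to 19.4 ± 1.65 and 8.71 ± 1.89 (edgeR adjusted p = 1.03e-05 and 0.000149), and Slc26a3, an anion exchanger of the gut, had 8 counts in the controls and ratios of 22.4 (11.2 to 52.6) and 15.9 (7.90 to 37.6). Ttc6, the neighbour of Foxa1 (chromosome 12, 57564113 to 57737928), rose from 0.186 ± 0.08 CPM to 1.91 ± 0.42 and 3.13 ± 1.13 (edgeR adjusted p = 0.00687 and 0.00198), while Mipol1 on the other side of Foxa1 had 3.15 ± 0.53, 3.70 ± 0.55 and 2.94 ± 0.41 (edgeR adjusted p = 0.578 and 0.836).

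Other genes set the libraries labelled Grg3 Grg4 mutant apart. Raet1d and Raet1e, which encode ligands of an activating receptor of natural killer cells, overlap on chromosome 10. Raet1d had 9 counts in these libraries, against 250 in the controls and 344 in the libraries labelled Grg3 mutant, ratios of 34 (17.6 to 75.1) and 37.3 (19.4 to 82.2). Raet1e had 0.209 ± 0.04 CPM against 2.70 ± 0.16 and 1.97 ± 0.28 (edgeR adjusted p = 0.000307 and 0.00219). The splicing-related genes Srek1 and Rbm25 and the nuclear anchoring protein gene Akap8 rose by 1.51-fold, 1.42-fold and 1.45-fold against the libraries labelled Grg3 mutant (edgeR adjusted p = 0.0325, 0.0294 and 0.0311), in the same libraries as the higher share of reads outside annotated genes. Pnn and Clk1, looked at alongside, had 1.57-fold and 1.45-fold and did not pass (edgeR adjusted p = 0.0505 and 0.132), and no list of splicing genes was tested. The metallothionein genes Mt1 and Mt2 rose 5.79-fold and 18.0-fold in the libraries labelled Grg3 mutant against control (edgeR adjusted p = 0.04 and 0.0311), and in those labelled Grg3 Grg4 mutant 2.93-fold and 5.92-fold without passing (edgeR adjusted p = 0.113 and 0.0855).

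Tle3, Foxa1 and other genes set apart the control libraries. Liver RNA is argued against as their common source. The ratio of a liver gene to Foxa1 spanned a median of 13.3-fold over the 6 libraries labelled mutant, while Foxa1 stayed between 10.5 and 14.4 CPM. Stomach or intestine stays open. Of 26 genes of their lists, 2 (7.69%), Lgals4 and Apob, lay above all controls in all 6, but 14 of the 26 were under 1 CPM in the controls. Gast, Nkx6-3 and Slc26a3, which are in neither list, were higher. Tff2 of the stomach list was lower, at 89.4 to 134 CPM in the controls and 30.4 to 80.3 CPM in the other 6 libraries. An exchange of labels between control and 1 mutant group is argued against by the smaller Tle3 change of 1.05, if a deletion lowers the transcript; control libraries from embryos of another genotype stay open. Strain or allele differences stay open: the odds ratio of pseudogenes among the 128 shared calls was 0.879 (0.391 to 1.73, Fisher's exact p = 0.869). This met the bound of under 2 set beforehand, but that bound was wrong, as the interval includes 1 and such differences need not fall on pseudogenes. Of the 19 nearly on or off genes, 4 (21.1%) lay within 5 Mb of another, too few to tell: Foxa1 with its neighbour Ttc6, and Gdf2 with Itih4. Only liver list members were left out of the 19. Other genes expressed in liver stayed in, among them Kng1, Apob, Plg, Serpina1e, Itih4 and Gdf2. Over the 6 libraries Kng1 and Apob were lowest in Grg3 mutant replicate 2, as Alb was. The pair of Gdf2 with Itih4 therefore cannot be told apart from the liver pattern. Sex is argued against for Tle3 and Foxa1, which passed with sex as a term and stood at 63.1 and 0.0418 CPM in the male control against 148 and 14.4 CPM in the male library labelled Grg3 mutant, while the mutations and a mixed background that differs between litters may each contribute and were not separated here.

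Of 18 liver genes, 9 were called higher for the label Grg3 mutant and 11 for Grg3 Grg4 mutant, and all 18 were above 0 in both. The list calls were lost with an estimated correlation (limma adjusted p = 0.258 and 0.196). A hypothesis is that pieces of liver came along in the dissection: over the 6 libraries the first component of 18 liver genes held 88.4% of their variance (random lists of the same size: median 55.0%, highest 97.5% of 1000), with Alb from 37.9 to 810.5 CPM against 2.37 to 5.47 in the controls. Of the 18, 5 reached 1 CPM in every control library and 0 belong to another fixed list. The Foxa1 level alone is argued against, as the liver genes spanned 13.3 times the fold of Foxa1 over these libraries. A liver programme switched on together in pancreatic cells would also give 1 component and stays open, as does an effect of the mutations.

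Of 34 acinar enzyme genes, 9 were called lower for the label Grg3 mutant and 11 for Grg3 Grg4 mutant, by unequal amounts. The list calls were lost with an estimated correlation (limma adjusted p = 0.258 and 0.196). A lower acinar share alone would lower all acinar enzyme genes alike. The 95% interval excluded the list's median for 9 of 34 genes in the libraries labelled Grg3 mutant and for 8 in those labelled Grg3 Grg4 mutant. These unequal falls go against that explanation but do not settle it. The cut of at least 8 genes was set after the results were seen, and the lower count equals it. The list also holds trypsinogen genes whose single values are uncertain. Reads moved among the counted trypsinogen copies are argued against as the whole cause for that family. The sum of 10 trypsinogen genes, chosen after their values were seen, changed by -1.15 (-1.85 to -0.44) and -1.13 (-1.48 to -0.79) on the log2 scale. Reads of these genes that aligned to several places are not in the sum, so a loss of reads to them stays open. Within the family, Gm5771 and Gm10334 were 6.67-fold and 5.92-fold lower for the label Grg3 mutant, while Prss2 (1.14-fold lower) did not pass. An effect of the mutations on some enzyme genes may remain, and allele differences within the trypsinogen cluster were not tested.

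With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. With only the 6 libraries of a comparison in the edgeR fit, the real split called 255, 750 and 10 genes and was the 1 split with as many in each comparison. The highest of the other splits was 1, 0 and 3.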
